A study of Homo sapiens with 2 samples.

How the data were processed

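The series measured total RNA of S2-013 cells, a pancreatic cancer cell line, on Affymetrix whole-transcript arrays. Both samples were cells with HOXB7 knocked down and then given a plasmid that re-expresses HOXB7. They differed in whether a MEK inhibitor was added. MEK is the kinase that phosphorylates and activates ERK in the RAS-RAF-MEK-ERK cascade. There was 1 array with the inhibitor and 1 without it, and each sample was assigned to its group from its title. Neither the inhibitor's name, its dose nor the exposure time is given in the sources used here. Per the labels' protocols, RNA was purified with the RNeasy kit, and 100 ng per sample was made into biotinylated sense-strand cDNA with the GeneChip WT PLUS Reagent Kit.

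The table the authors deposited holds 1 value per probe set and array on a log2 scale. The scale is inferred from the values, which ran continuously from 1.16 to 13.4, and every fold given here assumes it. The submitters' processing notes name Affymetrix Expression Console version 1.3. The background correction, summarisation and normalization settings are not given in the sources used here. The arrays had nearly equal quantiles: medians were 3.46 with the inhibitor and 3.49 without it, and the 95th percentiles were 8.25 and 8.24. The values were therefore used as deposited. A method that brings quantiles together removes any difference in total RNA output between the cultures, and whole-transcript summaries compress large folds. No detection calls or scanner intensities were used, so whether a dim probe set was above background is unknown.

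Of 53617 probe sets, 16098 had 1 gene symbol in the platform annotation and none had several. The other 37519 are unnamed here. All 16098 Entrez identifiers were found in the reference gene table, which changed no symbol. Probe sets whose symbol starts with MIR or SCARNA (1264 and 23 probe sets) were kept apart as small RNA, host genes of microRNAs included. For each remaining gene the probe set with the highest mean of both arrays was used, which gave 13763 genes, 655 of them with more than 1 probe set. A gene was kept when the higher of its values reached 4.78, the median over genes of the mean of both arrays. This level is called the floor, and 7164 genes passed it.

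The difference of log2 values, inhibitor minus no inhibitor, was computed per gene, and genes past 2-fold were counted. With 1 array per group there are no replicates, so no test was run and no p-value or standard error exists for any gene. The only error that could be measured was the disagreement between probe sets of the same gene, which covers probe error within these arrays and not the variation between cultures. Each of 37 gene lists had its median difference set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called outside when its median lay beyond the central 95% of those medians. This percentile describes these arrays only. Genes of a pathway move together between any 2 cultures, so a list outside the range is not evidence about the inhibitor by itself. A list with fewer than 3 members above the floor got no median.

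The lists, the floor, the 2-fold threshold, the alternatives and the rule for named genes were fixed before the data were examined. The rule names HOXB7, the 12 genes with the highest and the 12 with the lowest difference, up to 4 members of each list with the largest differences, and any member of the ERK target and RAS-RAF-MEK-ERK lists. Symbols of uncharacterised loci, long non-coding RNAs and antisense genes were passed over. The alternatives were subtracting the median difference or a loess trend on the mean, no filter and a 75th percentile filter, averaging the probe sets of a gene, thresholds of 1.5-fold and 3-fold, and leaving out each list's member with the largest difference.

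The procedure was tested on simulated data made from the 7164 genes. In each expression bin, differences beyond the central 95% were set to its bounds, so that genes with real changes would not count as unchanged, and the differences were then shuffled. Genes shifted by 1.5 on the log2 scale were called past 2-fold in 98.0% of cases upwards and 94.0% downwards, and those shifted by 2 in 100% of cases. These shares hold for the narrowed spread, and the simulation gives no rate of false calls, since it took away the extreme differences. Lists of 10 genes shifted by 0.3 fell outside in 84.0% of 200 draws, and unshifted lists in 5.0%. The share for unshifted lists follows from the shuffling, so it gives no rate of false calls for lists whose members move together. Lists of fewer than 10 genes were not simulated. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. The replication-dependent histone list had no member named on the array and is not analysed here.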

Results

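Per the series' design text, the arrays were run to look for factors and pathways under the control of MEK signalling linked to HOXB7, a homeobox transcription factor. Expression was compared between S2-013 cells with knocked-down and re-expressed HOXB7 that received a MEK inhibitor and the same cells without it. Each condition was measured on 1 array, so no value below has a replicate error. The 2 arrays correlated with Pearson's r of 0.988 over 53617 probe sets and 0.969 over the 7164 named genes above the floor. Both are correlations across genes, which are not independent replicates. Among 443 pairs of probe sets that read the same gene, the log2 differences disagreed by a median of 0.16 and by up to 0.80 in 95% of pairs. The pairs came from 145 genes, and 45 genes with identical copies were left out. Genes with many probe sets give many pairs, which are not independent. In 2.03% of pairs the disagreement was 1 or more. Differences below about 0.80 for a single gene are therefore within the disagreement seen between probe sets.

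HOXB7 itself had nearly the same level in both arrays. Its probe set (16846271) read 5.85 with the inhibitor and 5.84 without it, a log2 difference of 0.01. No array of parental or knockdown-only cells was analysed here, so the level before rescue is unknown, and a probe set may not read the plasmid's transcript in full. HOXB6 had a difference of -0.47 and HOXB9 of -0.05, and the median of the 3 measured HOXB genes was -0.05, inside the range of random lists. The other 7 HOXB genes lay below the floor in both arrays. Of the 21 named genes among the other HOX genes and their PBX and MEIS cofactors, only PBX2 (0.05) and PBX4 (0.12) were above it.

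All 17 measured members of the list of ERK feedback regulators and direct ERK targets were lower, 9 of them by at least 2-fold, and the list's median difference was -1.002. None of the 10000 matched random lists had a median as low. SPRY4, a Sprouty inhibitor of receptor tyrosine kinase signalling, was 4.44-fold lower, and SPRY2 had a difference of -1.002. The list's dual-specificity phosphatases, which dephosphorylate MAP kinases, were also lower: DUSP4 by 3.69-fold, DUSP6 by 2.39-fold and DUSP5 by 2.19-fold. Of those held in other lists, DUSP1 read 0.27, DUSP2 -0.08 and DUSP7 -0.49. The 3 ETS factors of the PEA3 family had differences of -1.75 (ETV4), -1.72 (ETV1) and -1.55 (ETV5). The pseudokinase gene TRIB1 had a difference of -1.13. Smaller differences were read for the kinase receptor gene EPHA2 (-0.67), the cytokine gene LIF (-0.53), MYC (-0.35), the AP-1 subunit gene FOSL1 (-0.31) and the cyclin D1 gene CCND1 (-0.14).

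DUSP5 and TRIB2 each had 2 probe sets that disagreed. For DUSP5 these read -1.13 and -0.13, and for TRIB2 -0.998 and 0.06. Averaging the probe sets of each gene, or keeping only the 11 members above the 75th percentile, gave a list median of -0.67.

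**Figure D1:**
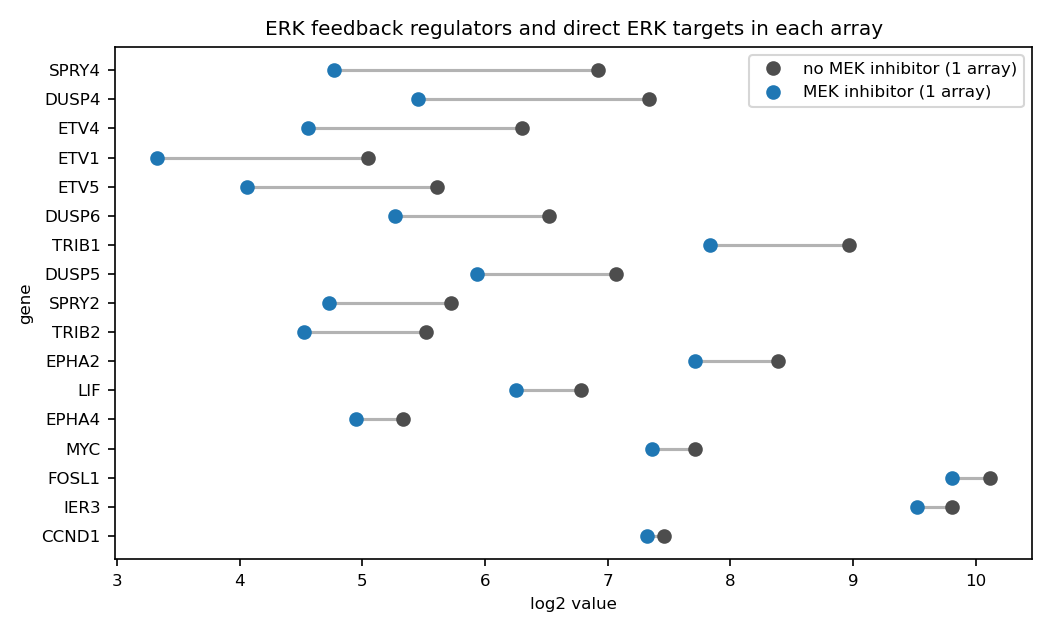
Log2 value (horizontal axis) of each of the 17 measured ERK feedback regulators and direct targets (vertical axis), with 1 point per array and a line joining the arrays. Every gene reads lower with the MEK inhibitor, from -2.15 for SPRY4 to -0.14 for CCND1.

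Across all genes above the floor, 45 were at least 2-fold higher and 75 at least 2-fold lower with the inhibitor, together 1.68% of the 7164. This share is no larger than the 2.03% of same-gene probe set pairs that disagreed by 1 or more. A pair holds the error of 2 probe sets, so the shares are not directly comparable. The count alone therefore does not separate these genes from probe error. With the 75th percentile filter, 24 were higher and 52 lower. At 1.5-fold the balance turned, with 331 higher and 258 lower. EGR1, an early growth response transcription factor induced through ERK, had the lowest difference, -2.94 (8.13 without and 5.19 with the inhibitor). Its second probe set read -1.19. MMP1, the interstitial collagenase, was the brightest of these genes and 5.78-fold lower (11.3 without and 8.81 with the inhibitor). TNS4, a focal adhesion tensin, was also 5.78-fold lower, followed by the secreted glycoprotein gene STC1 (5.30-fold) and the ephrin receptor gene EPHA7 (4.88-fold). DHRS3, a retinal reductase, was 3.76-fold lower. CEACAM6, a cell surface adhesion protein, was 3.72-fold lower, the homeobox gene LHX1 3.66-fold and the chromatin protein gene HMGA2 3.39-fold. SPRY4, DUSP4 and ETV4 complete the 12 lowest. With the inhibitor EPHA7, HMGA2, SPRY4, SPRY2, TRIB2, ETV1, ETV4 and ETV5 were below the floor, so their folds end in dim signals.

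Among the genes with the highest differences, CCL20, a chemokine that attracts CCR6-bearing lymphocytes, was 5.23-fold higher (3.63 without and 6.01 with the inhibitor). The cytokine gene IL32 was 3.43-fold higher, the chemokine gene CXCL10 3.10-fold and the TNF receptor adaptor gene TRAF1 2.99-fold. EDIL3, an extracellular matrix protein that binds integrins, was 4.41-fold higher. NBEA, a trafficking protein, was 3.37-fold higher, and the lipid phosphatase gene PLPP1 3.03-fold. ABHD4, a lipase of N-acyl phospholipids, was 2.96-fold higher, the caveola component gene CAVIN1 2.88-fold and the laminin-related gene NTN4 2.66-fold. CNTNAP1 (2.65-fold) and the phosphatase methylesterase gene PPME1 (2.60-fold) complete the 12 highest. CCL20, EDIL3, IL32, NBEA, TRAF1 and CNTNAP1 were below the floor of 4.78 without the inhibitor, so their folds start from dim signals.

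**Figure D2:**
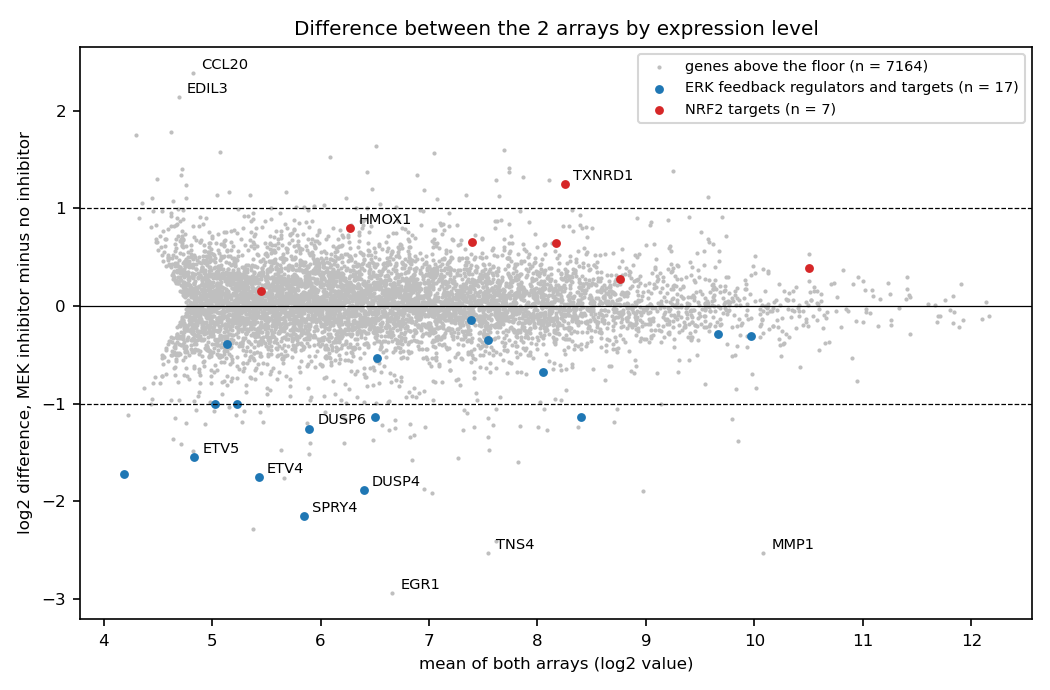
Log2 difference, MEK inhibitor minus no inhibitor (vertical axis), against the mean log2 value of both arrays (horizontal axis), for 7164 genes with 1 array per group; dashed lines mark 2-fold. The 17 ERK feedback regulators and targets all lie below 0 and the 7 NRF2 targets all lie above it.

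Of 17 immediate early genes measured, 9 were lower and 8 higher, and the list's median of -0.08 lay inside the range of random lists (mean -0.22). For the 11 members above the 75th percentile the median was -0.33, outside the range (percentile 0.03). EGR1 and KLF2, a Kruppel-like factor (-1.16), were lower by at least 2-fold. The AP-1 subunit gene JUND read 1.02 and JUN 0.62. Among components of the RAS-RAF-MEK-ERK cascade, the MEK1 gene MAP2K1 read 0.02, the ERK1 gene MAPK3 0.14 and ARAF 0.02, and the lowest was HRAS at -0.59; the median of 10 members was -0.03. EGF family ligands had a median of -0.05 over 3 members, with BTC at 0.64 and EREG at -0.05. Receptor tyrosine kinases had a median of -0.02 over 11 members, with ROR1 at 0.73, DDR1 at 0.43, MST1R at -0.41 (-0.24 over its 2 probe sets) and FGFR4 at -0.71. That median was 0.10 without the filter, and 0.35 and outside the range for the 5 members above the 75th percentile (percentile 98.7). Means of the EGF ligand and receptor kinase lists were above 0 (0.14 and 0.02), against medians below it.

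Of 12 ribosome biogenesis genes measured, 11 were lower, none by 2-fold, and the median of -0.33 lay at the 0.01 percentile of random lists. The snoRNP methyltransferase gene FBL and the processing factor gene BOP1 both read -0.68, nucleolin (NCL) -0.59 and WDR74 0.50. The second probe set of BOP1 read -0.28. Of 20 mitotic genes, 17 were lower, none by 2-fold, the median was -0.15 (percentile 0.60), and the lowest were the kinase gene PLK1 (-0.51) and the kinesin gene KIF20A (-0.44). DNA replication genes had a median of -0.04 and a mean of 0.00 over 21 members, inside the range, with MCM10 at -0.44 and GINS2 at 0.36. Cytoplasmic ribosomal protein genes had a median of -0.09 over 21 members, inside the range, with RPL6 at -0.60 and RPS16 at 0.41.

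Lists of cell cycle exit and survival genes stayed inside the range of random lists. The list of CDK inhibitors and cell cycle exit genes had 4 members above the floor, with a median of 0.11. These were RBL2 (0.16), FOXO1 (0.37), FOXO3 (0.05) and FOXO4 (-0.45). None of the list's CDK inhibitor genes was named on the array, so this median says nothing about them. The BCL2 family had a median of -0.02 over 10 members. Within it the prosurvival gene MCL1 read -0.61, the BH3-only gene PMAIP1 -0.68 and BAD 0.62. The p53 targets had a median of -0.03 and a mean of 0.13 over 9 members, with TP53I3 at 1.11 and SESN2 at 0.55. The 5 members above the 75th percentile had a median of -0.23, inside the range.

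Of 20 epithelial junction and polarity genes, 17 were higher, none by 2-fold, with a median of 0.20 (percentile 99.5). The claudin genes CLDN4 (0.95) and CLDN3 (0.93), the desmocollin gene DSC2 (0.85) and the transcription factor gene GRHL2 (0.45) had the largest differences. The other 3 genes were lower. The E-cadherin gene CDH1, a member of this list, was not named on the array. With the 75th percentile filter the median of 0.16 fell inside the range (percentile 97.3). Of 6 mesenchymal genes above the floor, 4 were lower, with a median of -0.27 (percentile 1.17) and a mean of -0.10. SNAI2, a repressor of epithelial genes, read -1.09 and vimentin (VIM) -0.39 (-0.61 over its 3 probe sets), whereas the collagen cross-linking enzyme genes LOX and LOXL2 read 0.76 and 0.64. Without SNAI2 the median was -0.25, inside the range (percentile 2.64).

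Markers of both pancreatic cancer subtypes were mostly below the floor. The 5 basal-like markers above it had a median of -0.40 (percentile 0.26), with TNS4 lowest (-2.53) and VGLL1 at 0.56. With all 11 named members the median was -0.14, inside the range. The 3 classical markers above it had a median of -0.31, inside the range, with CEACAM6 at -1.90, TFF3 at -0.31 and GATA6 at 0.10. Among matrix proteases MMP1 stood apart from the rest. The list's median was 0.22 and its mean -0.18, since 6 of 9 members were higher, among them TIMP2 (0.42) and ADAM17 (0.40), while MMP1 and TIMP1 (-0.64) were lower. That median lay at percentile 97.1, inside the range, and outside it under each alternative except subtraction of the median difference. The 7 measured YAP-TEAD targets were all higher, with a median of 0.28 (percentile 98.1). The LIM protein gene AJUBA (0.87) and the scaffold gene WWC1 (0.80) had the largest differences, and without AJUBA the median of 0.24 lay inside the range. For the 4 members above the 75th percentile the median of 0.28 also lay inside it (percentile 95.5). The TGF-beta list had a median of -0.14 over 6 members, inside the range, with 3 members higher and 3 lower, among them SMAD6 at -0.72 and BAMBI at -0.54. It turned to 0.027 without the filter and without SMAD6. Of the integrin and laminin list only CD44 was named on the array (-0.19).

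The list of NF-kappaB cytokines and targets had a median of 0.36 (percentile 99.6), with 6 of 8 members higher. Besides CCL20, the adhesion receptor gene ICAM1 was 2.18-fold higher, the NF-kappaB subunit gene RELB read 0.54 and the chemokine gene CXCL5 0.41. Without the filter the median was 0.23, outside the range (percentile 99.2). Interferon-stimulated genes had a median of -0.02 and a mean of -0.20 over 24 members, with the median inside the range. Within them OASL (-1.19), RSAD2 (-1.06) and IFIT2 (-1.05) were lower by at least 2-fold, and none was 2-fold higher. The 4 measured genes of MHC class I antigen presentation were all higher, from 0.17 (B2M) to 0.66 (TAPBP), with a median of 0.25 inside the range (percentile 96.2).

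All 7 measured targets of NRF2, the transcription factor of the oxidative stress response, were higher, with a median of 0.64 at percentile 100. Thioredoxin reductase (TXNRD1) was 2.38-fold higher, and the differences were 0.80 for heme oxygenase (HMOX1), 0.65 for sulfiredoxin (SRXN1) and 0.64 for the pentose phosphate enzyme gene TALDO1. Of 14 cholesterol biosynthesis genes, 13 were higher, none by 2-fold, with a median of 0.27 (percentile 99.8). The largest differences were those of INSIG1 (0.90), MSMO1 (0.59), MVD (0.51) and HMGCS1 (0.50). The other metabolic and stress lists had medians inside the range. Glycolysis and hypoxia genes had a median of 0.07, with BNIP3 2.58-fold higher and NDRG1 at -0.53. Oxidative phosphorylation subunits had a median of 0.07, with COX7B at 0.38. Genes of the amino acid and unfolded protein responses had a median of 0.05, with ASNS at 1.02 and DDIT3 at 0.65. Lysosome and autophagy genes had a median of 0.11, with LAMP2 at 0.65 and SQSTM1 at 0.44. Their median was 0.24, outside the range, both without the filter (percentile 99.7) and with the 75th percentile filter (percentile 99.0).

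Of 31 lists with a median, 10 lay outside the central 95% of random lists, 5 above and 5 below. If the members of each list moved like randomly drawn genes, 1.55 lists would lie outside on average. Genes of a pathway move together, so no chance rate is known for these lists. Housekeeping genes had a median of 0.02 over 6 members, with PGK1 at 0.36, B2M at 0.17, HPRT1 at -0.12 and TBP at -0.08. Markers of other cell types were mostly below the floor. Of 6 named fibroblast markers 1 reached it (DES, -0.54, and -0.21 in its second probe set). It was also reached by 2 of 8 endothelial markers (ESAM, -0.63, and CLDN5, -0.06) and 1 of 7 acinar and endocrine markers (CTRC, 0.30). Of 7 leukocyte markers 3 reached it, CD68 (-0.43), TYROBP (-0.39) and LYN (-0.33), with a median of -0.39 inside the range (-0.047 over all 7). The 1287 small RNA probe sets had a median difference of -0.04 with an SD of 0.30 between probe sets, and 2 were at least 2-fold higher and 11 at least 2-fold lower.

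**Figure D3:**
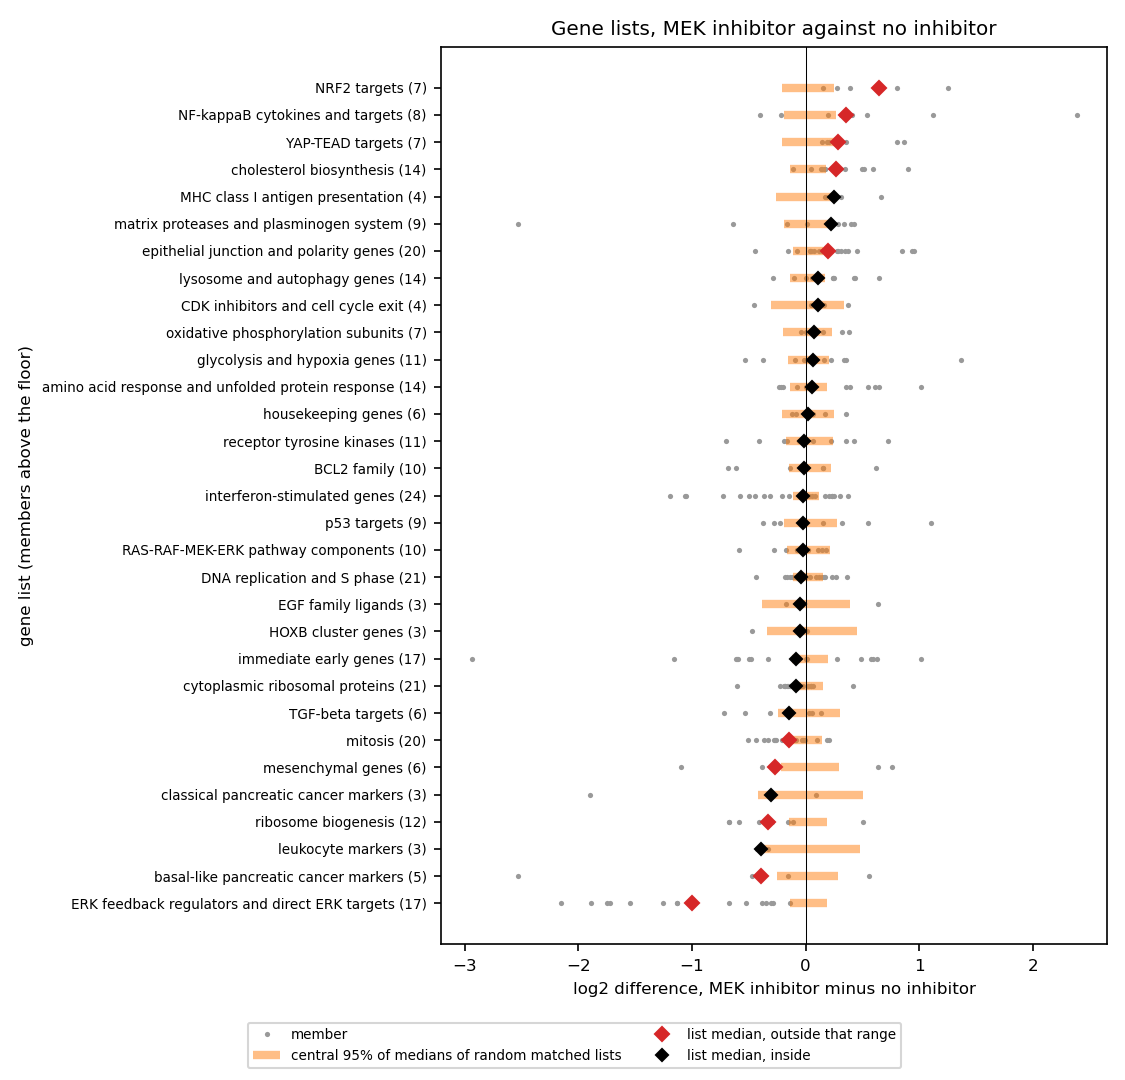
Log2 difference, MEK inhibitor minus no inhibitor (horizontal axis), of the members above the floor (grey points) and the median (diamonds) of 31 gene lists, with 1 array per group; orange bars span the central 95% of medians of 10000 matched random lists. The 10 red medians lie outside their bars, from -1.002 for the ERK list to 0.64 for the NRF2 list.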

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

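Differences of 2-fold or more were also read in probe sets that the comparisons did not use because they are unnamed here. Of 9010 unnamed probe sets above the floor, 104 were at least 2-fold higher with the inhibitor and 126 at least 2-fold lower, together 2.55%. The largest difference read was 3.43 on the log2 scale (probe set 16654281, 1.78 without and 5.21 with the inhibitor). The value without the inhibitor lies below that array's 5th percentile (1.88), so the size of this difference is not reliable. The lowest was -2.55 (probe set 16738803, 6.56 without and 4.01 with the inhibitor), which ends below the floor. These are values of 1 array per group, and neither sequence nor gene was assigned to these probe sets.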

How the results depend on the processing

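No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Subtracting the median difference (46 higher, 74 lower) or the loess trend (44 higher, 75 lower) barely moved the 2-fold counts, and since both corrections were small they are weak tests of the scaling. Omitting the filter gave 56 and 86 and averaging probe sets 45 and 72. The 75th percentile filter left 24 genes higher and 52 lower among 3677 tested. At 1.5-fold the counts were 331 higher and 258 lower, so more genes were higher than lower, the opposite of the 2-fold counts, and at 3-fold they were 6 and 14. All 10 lists outside the range of random lists stayed outside under both scalings and with averaged probe sets, and no called list reversed its direction. Without the filter the basal-like list (-0.14) lost its place outside the range. With the 75th percentile filter the epithelial list (0.16) and the YAP-TEAD list (0.28) did, and without the top member the mesenchymal (-0.25) and YAP-TEAD (0.24) lists did. The ERK list read -0.67 with the 75th percentile filter and with averaged probe sets, below all random lists in each case. Medians that moved with the 75th percentile filter were those of immediate early genes (-0.33), receptor tyrosine kinases (0.35), p53 targets (-0.23) and lysosome genes (0.24), and the first, second and last of these then lay outside the range. Without the filter receptor tyrosine kinases (0.10), TGF-beta targets (0.027), NF-kappaB targets (0.23), lysosome genes (0.24, outside the range) and leukocyte markers (-0.047) moved. Leaving out the top member moved TGF-beta targets (0.027) and NRF2 targets (0.52). In all, 161 alternative list medians moved by less than the SD of random lists' medians and 14 by more. Of alternative values of named genes, 329 moved by less than the median disagreement of probe sets and 7 by more. Each scaling left all 31 list medians and all 160 gene values within these bounds. Subtracting the median difference of -0.006 shifts every gene alike, so its outcome was fixed beforehand. Averaging probe sets moved 7 gene values and left 9. The largest move of a gene was that of EGR1, to -2.06 with averaged probe sets. Beyond the smaller memberships after filtering, the causes were not tested. Signal over background is unknown here, which limits every gene near the floor.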

Other observations

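The tests with second gene lists were set up before their values were seen. Their members were genes outside the first lists that had not been seen among the extreme genes. Leaving out the top member was an alternative fixed before the data were examined. Its use as a test of a single member (NF-kappaB list) was chosen after the list medians were known. So was the test of other differences between the cultures. A trend with intensity between the arrays was not tested apart from the matching of random lists on expression and the loess alternative, which moved too little to decide.

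Further genes, not described above, moved with the NRF2 and NF-kappaB lists. Of 10 further NRF2-related genes above the floor, 8 were higher, with a median of 0.32 (percentile 99.9 of random lists). The biliverdin reductase gene BLVRB read 0.81, the ferrochelatase gene FECH 0.80, UGDH, which makes UDP-glucuronate, 0.75, and the NRF2 inhibitor gene KEAP1 0.56. Of 13 further NF-kappaB-related genes, 12 were higher, with a median of 0.34 (percentile 99.9). The chemokine genes CCL5 (0.67) and CXCL11 (0.50), the subunit gene NFKB2 (0.60) and the apoptosis regulator gene CFLAR (0.49) were the highest. No member of either second list reached 2-fold, an outcome made likely by leaving out genes seen among the extremes.

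The ERK feedback regulators and targets were lower in all 17 measured cases. A wider set of ERK-dependent genes had 8 of 10 members lower but a median of -0.13 (percentile 5.30). That does not settle whether ERK-dependent genes outside the first list were lower in general. Genes seen among the extremes could not enter the wider set, which makes a low median less likely. With 1 array per group, the inhibitor named in the labels and any other difference between the 2 cultures cannot be told apart, since nothing measures the spread between cultures.

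The NRF2 targets were higher in all 7 measured cases. The second list (0.32) is consistent with a response of the pathway as a whole, which remains a hypothesis. Whether the inhibitor, its solvent or the state of the culture set it apart is open, as no further array of either condition was analysed here.

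The NF-kappaB list had a median of 0.36, and of 0.31 without CCL20 (percentile 97.9, close to the edge of the central 95%). The second list (0.34) points the same way without CCL20 or ICAM1. A broader NF-kappaB response may therefore accompany the lower ERK targets, as a hypothesis from 1 array per group. Interferon-stimulated genes as a list had a median of -0.02, although CCL5 and CXCL11 also respond to interferon.

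A copy number difference between the cultures was tested through the median difference of each autosome. The farthest from 0 was chromosome 14, at 0.088 over 211 genes, and all 22 autosomes lay within the range of random gene sets of their size. That range was set at a level of 0.05 divided by 22, so it is wider than the central 95% used for the lists. Chromosome 14 lay near its upper edge of 0.098, and chromosome 6 (0.075) near its upper edge of 0.084. The bound of 0.1 set beforehand lies close to these edges, so a small whole-chromosome difference stays open, and smaller segments were not tested.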
